A study of Homo sapiens with 15 samples.

How the data were processed

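Poly(A) RNA of cultured cells labelled as human monocytes was sequenced in 15 libraries, 3 in each of 5 groups: medium alone, live *Brugia malayi* microfilariae (Mf), extracellular vesicles (EVs) of Mf, excretory and secretory products of Mf (E/S), and EV-depleted E/S. Per the labels' protocols, exposure lasted 48 h at 37 °C in 5% CO2, only RNA with an integrity number of 8 or more went into a stranded poly(A) library kit, and read pairs of 151 nt were sequenced. The group and the replicate number of each library were taken from its title. The labels do not say that a replicate number stands for a donor. For EVs and live Mf, libraries of one number deviated alike. Their deviations from the group means had correlations of 0.46, 0.15 and 0.453, against −0.423 to 0.01 for different numbers. Each of the 6 libraries correlated best with its own number. With the trends on GC content and length removed the correlations were 0.157, 0.158 and 0.191, against −0.123 to −0.041. This comparison was singled out from these same values. Deviations from a mean of 3 libraries cancel, so high correlations of one number come with low ones of other numbers. Libraries of one number also held the same rank in the trend of expression on GC content. Elsewhere different numbers reached 0.368 (EV 3 with EV-depleted E/S 2). The pairing can therefore be chance, and what the pairs would share is not given.

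The values are expected counts per gene, as deposited by the authors in one table with a column for each library. Per the submitters' processing notes, cutadapt 1.18, STAR 2.7.6a and RSEM 1.3.0 were used with the human build hg38/GRCh38. The notes give no role or order to these tools. RSEM estimates how many read pairs belong to each gene and divides pairs that match several genes between them. Counts of genes with close paralogs or processed pseudogenes therefore depend on that division, and genes known to have such copies are named as uncertain. The annotation release and any filter are not given in the sources used here. Of the deposited values, printed with up to 2 decimals, 7.23% differed from a whole number by 0.01 or more, and no scaling between libraries was seen, since the totals differed from 16454752 to 23154534. The counts come from PCR-amplified reads without molecular identifiers, so counting error understates the error of a value, and the spread between libraries was used for all tests.

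Of the 58381 genes in the table, 58261 (99.8%) matched a gene of GENCODE release 29 on GRCh38 by identifier, which gave symbols, coordinates, GC content and transcript lengths. Sex-linked genes, 567 in number, were left out of the tests, tables and plots so that nothing about a donor could be read from them. Genes with a sequence that varies strongly between people and genes known only by a clone name were not named.

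Expected counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3 (TMM normalization, filterByExpr by group with a minimum count of 10 and a minimum total of 15, estimateDisp, robust glmQLFit and glmQLFTest). All 15 libraries entered one fit with 10 residual degrees of freedom, and each comparison was a two-sided contrast with Benjamini-Hochberg adjustment and a threshold of 0.05. After the filter 14953 genes were tested. The biological coefficient of variation was 7.58%. Contrasts were fitted for each of the 4 exposures against media, E/S against EV-depleted E/S, and EVs against live Mf. CPM values (counts scaled to a common library size) of tested genes in a comparison use the TMM-scaled library size. The plain total was used for untested genes, whole lists and their members, levels over all 15 libraries, and the count of genes under 1 CPM among 21 immune genes. Errors of log2 fold changes are standard errors derived from the quasi-likelihood F statistic.

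These choices were made before the data were examined: the tests, the contrasts, 24 pathway lists, 10 marker lists and the rule for naming genes. Lists with at least 5 tested members, 28 of the 34, were tested with camera from limma 3.58.1 at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison. camera with an estimated correlation and fry were alternatives. The lists were interferon-stimulated, interferon-gamma response, inflammatory, alternative activation, regulatory, class II and class I presentation, costimulatory, metallothionein, glycolysis, hypoxia, oxidative phosphorylation, ATF4, mTOR, lysosome, cholesterol, lipid handling, NRF2, chaperone, pattern recognition, matrix, p53, cell cycle and ribosomal protein genes, and markers of classical and non-classical monocytes, macrophages, T, NK and B cells, platelets, neutrophils, dendritic cells and red cells. The counts "adjusted over the list alone" repeat the Benjamini-Hochberg adjustment within a list.

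Genes were named by a rule. In each comparison these were the 10 higher and 10 lower genes with the largest fitted change among those past the threshold, with a mean of at least 1 CPM and with every library of the first group on one side of the mean of the second. To these were added up to 4 members with the smallest p of each list that was called or had a member past the threshold, and 21 immune genes fixed in advance. Where fewer than 5 genes passed, the 5 with the smallest p were named as not having passed. The text leaves out some genes of this rule for length. CYP1B1 is named outside the rule in 4 comparisons, where it is said to have been chosen after its values were seen.

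Fold changes were seen to follow GC content, so a correction was added after seeing the data. For each library the trend of log2 CPM on transcript GC content and log length, fitted with natural splines of 5 degrees of freedom, was turned into offsets for the same edgeR test. GC content was known for 99.9% of tested genes. The trends on GC content and length were removed together, so a loss of calls cannot be assigned to either alone. The slope of a library is the linear trend, over 12823 genes with at least 1 CPM, of its log2 CPM deviation from the mean of all libraries. The other alternatives tried were RLE size factors, DESeq2 1.42.0 with a Wald test, no low-count filter, the replicate number as a block, only the 2 groups compared, each library left out in turn, thinning to the smallest library, EV 1 and live Mf 3 both left out, and the block in EVs and live Mf alone, also with the correction or with only these 2 groups. All from the thinning on were added after seeing the data.

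The scripts were tested on simulated counts drawn for the real genes, means and library sizes. Genes were drawn independently with one spread per gene for all groups, without GC trends unless stated, so the recovered shares may be too high. With 50 genes changed at each size between media and E/S, among 14774 genes in the fit, 24% of changes by 25%, 76% of 1.5-fold, 90% of 2-fold and 100% of 4-fold changes were recovered, with 8 false calls. The linear GC trends of the real libraries were then added to counts in which only 200 genes changed 2-fold. The test of E/S against media made 2138 false calls among 14804 genes, and the corrected test made 8 while recovering 184 of the 200. The correction was built to remove such trends, and the changed genes were picked at random. The simulation therefore does not show whether the correction also removes a real response that follows GC content. For the overlap of responses, 50 sets of 15 unchanged libraries were drawn around one mean per gene. Within groups, libraries differed by more than sampling noise in every pair (chi-square per degree of freedom from 2.36 to 22.3 over the pairs of a group), so no 2 of them were treated as copies of one library. This does not show that they came from separate cultures.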

Results

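The RNA of cells labelled as human monocytes was measured after 48 h of exposure to material from *Brugia malayi*, a filarial worm of the lymphatic vessels whose first-stage larvae, the microfilariae (Mf), circulate in the blood. The cells, at 1000000 per mL, received medium alone, 50000 live Mf, extracellular vesicles (EVs) shed by Mf at 10 µg of protein, 10 µL of the excretory and secretory products of Mf (E/S), or 10 µL of the same products after removal of the EVs (EV-depleted E/S). Each of the 5 groups had 3 libraries. The labels describe monocytes isolated from 4 donors, while the series title speaks of cell lines and the RNA protocol of dendritic cells. They do not say how the donors map onto the 3 libraries of a group, so the p-values measure the spread between these libraries, which may be technical. Totals ranged from 16454752 to 23154534 expected counts per library, with means of 18295021 ± 1663810 (SD, n = 3) in media, 20572465 ± 2024789 with live Mf, 21166923 ± 1166630 with EVs, 22631289 ± 659645 with E/S and 20512262 ± 339507 with EV-depleted E/S.

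Genes of dividing cells were abundant in all 15 libraries, and several surface genes of blood monocytes were scarce. The 24 cell cycle genes had a median of 224 CPM (counts scaled to one library size, as for each CPM value here; range over libraries 206 to 239), led by TOP2A, a DNA topoisomerase of dividing cells (1744 ± 133 CPM, SD, n = 15), and MKI67, a proliferation marker (553.2 ± 65.3 CPM). The 14 classical monocyte markers had a median of 16.5 CPM (14.6 to 18.4). CCR2, a surface receptor, led them at 342.8 CPM, followed by VCAN at 290.5 ± 22.1 CPM. CD14, the lipopolysaccharide co-receptor, was at 0.888 ± 0.359 CPM and FCN1 at 0 in every library. HLA-DRA, a class II antigen-presenting chain, was at 2.43 ± 0.433 CPM, LYZ, the lysozyme gene, at 386.8 ± 22 CPM and FCGR1A, a high-affinity antibody receptor, at 112.2 ± 7.43 CPM. Markers of other blood cells were near 0, with medians of 0.0207 CPM for 16 T cell, 0.0947 for 12 NK cell, 0.259 for 12 B cell, 0.039 for 13 platelet, 0.0948 for 10 neutrophil, 0.0457 for 12 dendritic cell and 0 for 10 red cell genes. Of 21 immune genes fixed in advance, 9 stayed under 1 CPM in every group mean. IL6 and IL10 had 2 counts each over all libraries, MRC1 had 5, IDO1 had 6 and CD80 had 11. Counts that low do not show whether these genes responded.

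The libraries differed in how expression followed the GC content of transcripts. The slope of each library's log2 deviation from the mean of all libraries was 0.190 ± 0.003 per 10 points of GC in media (SD, n = 3), 0.182 ± 0.137 with live Mf, −0.082 ± 0.175 with EVs, −0.141 ± 0.037 with E/S and −0.149 ± 0.082 with EV-depleted E/S. The 3 media libraries spanned 0.188 to 0.194, the live Mf libraries 0.040 to 0.314 and the EV libraries −0.245 to 0.103. Of the tested genes, 1306 with at least 1 CPM had a GC content of 60% or more and 2191 were under 40%. Between media and E/S the first class had a median log2 fold change of −0.63 and the second of 0.26. For this reason the GC content of many gene groups is given with their values below.

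**Figure D1:**
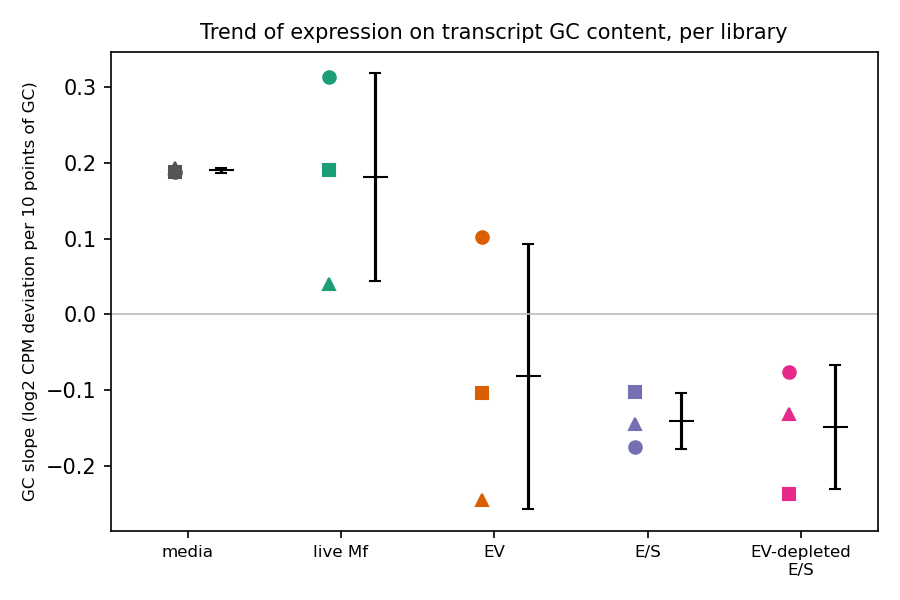
The slope of log2 CPM deviation on transcript GC content, in log2 units per 10 points of GC, is plotted for each of the 15 libraries by group, with circles, squares and triangles for replicates 1, 2 and 3 and black bars for the mean ± SD of 3 libraries. The media libraries sit between 0.188 and 0.194, and all 6 E/S and EV-depleted E/S libraries lie below them, at −0.077 or lower.

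Live Mf were compared with media to measure the response to whole parasites. No gene passed the test in this comparison. Among the genes with the smallest p was CYP1B1, which encodes a cytochrome P450 that oxidises hormones and aromatic compounds, at 244.3 ± 9.76 CPM in media and 314.2 ± 23.6 CPM with live Mf (SD, n = 3 each). Its log2 fold change was 0.36 ± 0.07 (SE), with an edgeR adjusted p of 0.388. ZC3HAV1L had a log2 fold change of −0.50 ± 0.10 and MPHOSPH6, an RNA exosome cofactor, of 0.34 ± 0.09. PTMA, with 0.21 ± 0.05, and NOTCH2NL, with −0.33 ± 0.08, completed the 5 genes with the smallest p of those that the naming rule admits. Both have near-identical copies that can share reads, so their values are uncertain. TNF, an inflammatory cytokine, was at 6.32 ± 0.39 CPM in media and 7.47 ± 1.04 CPM with live Mf, and MTOR, the kinase of the growth-control complexes, at 50.02 ± 2.09 and 46.1 ± 5.38 CPM. Neither passed.

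Among the lists fixed in advance, the cell cycle genes and the ribosomal protein genes were called higher with live Mf by camera. The 24 cell cycle genes had a median log2 fold change of 0.04 and a camera adjusted p of 0.0478, and the 40 ribosomal protein genes had a median of 0.03 and a camera adjusted p of 0.0412. No member of either list passed, nor did any when adjusted over the list alone, and both had a camera adjusted p = 0.917 with an estimated correlation. Median GC was 46.2% in the first list and 51.2% in the second. edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 0 of 14953 genes, with 546 at an unadjusted p under 0.05, and DESeq2 called 5, all higher. In simulated data with one spread per gene for all groups and no GC trends, this comparison recovered 90% of 2-fold changes and 34% of changes by 25%. The real live Mf libraries spread more in GC slope than media (0.040 to 0.314 against 0.188 to 0.194). The planted changes also eased the adjusted threshold, so the real shares may be lower. After each library's trend on GC content and transcript length was removed, CYP1B1 alone passed, with a log2 fold change of 0.38 and an edgeR adjusted p of 0.00438. This correction ended both list calls, with a camera adjusted p of 0.0611 for the cell cycle genes and 0.687 for the ribosomal protein genes, and neither list was called without media 3.

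Purified EVs were compared with media to measure what the vesicles alone do. Several transcripts for respiratory enzymes, ribosomal proteins and macrophage proteins fell. CYC1, the cytochrome c1 subunit of respiratory complex III (chromosome 8, 144095027 to 144097525 on GRCh38), was at 28.1 ± 0.96 CPM in media and 16.04 ± 4.02 CPM with EVs (SD, n = 3 each), a log2 fold change of −0.81 ± 0.15 (SE) with an edgeR adjusted p of 0.0271. TREM2, a lipid-sensing receptor of macrophages (chromosome 6, 41158506 to 41163186), went from 17.2 ± 0.84 to 10.2 ± 2.17 CPM. LGALS9, which encodes the immune-modulating lectin galectin-9, went from 29.1 ± 1.45 to 19.6 ± 4.55 CPM.

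Large falls were seen among scarce genes. Of those the naming rule selects, which have a mean of at least 1 CPM, ZDHHC12, a palmitoyltransferase gene, had a log2 fold change of −1.45 ± 0.35, QTRT1, which modifies transfer RNA, of −1.43 ± 0.29, and TRAF2, an adaptor of TNF receptors, of −1.09 ± 0.26. The GC content of these 3 genes was 64.6%, 61.6% and 61.3%. Among the largest rises by that rule were SOCS2, an inhibitor of cytokine signalling, at 0.99 ± 0.30, SH3BGR at 0.67 ± 0.21, and the zinc finger gene ZNF730 at 0.55 ± 0.13. SOCS2 rose from 0.718 ± 0.174 to 1.44 ± 0.214 CPM.

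Of 23 glycolysis genes (median GC 55.7%), 0 rose and 5 fell, or 0 and 9 adjusted over the list alone, with a camera adjusted p of 9.81e-04. Among them were GAPDH (−0.46 ± 0.13), PKM (−0.41 ± 0.12), TPI1 (−0.44 ± 0.10) and the hexokinase gene HK3 (−0.95 ± 0.25). Of 38 oxidative phosphorylation genes (median GC 47.8%), 1 rose and 7 fell, the same when adjusted over the list alone, with a camera adjusted p of 0.0422. COX8A fell by 0.70 ± 0.13 and COX4I1 by 0.48 ± 0.10 on the log2 scale. Of 40 ribosomal protein genes (median GC 51.2%), 0 rose and 12 fell, or 16 adjusted over the list alone, with a camera adjusted p of 2.53e-06. RPLP0 had −0.39 ± 0.10 and RPS16 −0.47 ± 0.11. GAPDH, TPI1 and the ribosomal protein genes have processed pseudogenes that can share reads. For all 3 lists the camera adjusted p = 0.642 with an estimated correlation. After the GC and length correction the glycolysis genes had 0 higher and 0 lower and were not called (camera adjusted p of 0.25). The ribosomal protein genes then had 1 higher and 0 lower, and the oxidative phosphorylation genes 0 and 2. Both lists were still called (camera adjusted p of 2.6e-04 each).

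Some genes of the immune lists moved with EVs. Of 17 class I presentation genes (median GC 55.3%), 1 rose and 4 fell, or 1 and 8 adjusted over the list alone, with a camera adjusted p of 0.0592. The GC and length correction left 1 higher and 0 lower and took their median from −0.24 to 0.07. Of 12 macrophage markers (median GC 52.7%), 0 rose and 3 fell, or 4 adjusted over the list alone: TREM2 (−0.75 ± 0.14), CD68 (−0.50 ± 0.14) and CHI3L1, a secreted glycoprotein (−0.33 ± 0.10). LGALS9 (−0.57 ± 0.13) was among 3 regulatory and inhibitory genes of 19 that fell, or 4 adjusted over the list alone. CD74, the class II invariant chain (−0.56 ± 0.13), was among 2 of 12 class II presentation genes that fell, as adjusted over the list alone. TNF (−0.45 ± 0.14) was 1 of 20 inflammatory genes to fall, 0 adjusted over the list alone. CD40, a receptor by which T cells activate myeloid cells, also fell (−0.50 ± 0.16). Of 20 pattern recognition genes, with a median of 0.08, 1 rose and 2 fell, NLRP3 (−0.27 ± 0.08) and MYD88 (−0.34 ± 0.08). Of 34 interferon-stimulated genes 1 rose and 1 fell, or 0 and 1 adjusted over the list alone. Of 12 alternative activation genes 1 rose and 0 fell. The other lists had a median GC of 42.9% to 52.7%, and the members named here 49.9% to 58.7%. After the GC and length correction the inflammatory, regulatory and macrophage lists each had 0 higher and 1 lower. No class II, pattern recognition, interferon-stimulated or alternative activation gene passed then.

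Some genes of cell division, chaperones and stress rose with EVs. Of 24 cell cycle genes (median GC 46.2%), 4 rose and 2 fell, or 5 and 3 adjusted over the list alone. TOP2A (0.23 ± 0.06, GC 39.1%) rose, and MCM5, a replication helicase subunit (−0.53 ± 0.13, GC 56.6%), fell. Of 20 chaperone genes, 3 rose and 1 fell, or 5 and 2 adjusted over the list alone, with HSP90B1 at 0.26 ± 0.06. Of 19 hypoxia response genes, 3 rose and 1 fell, the same when adjusted over the list alone, with ERO1A at 0.24 ± 0.07 and VEGFA, the vascular growth factor, at −0.32 ± 0.10. The zinc exporter SLC30A1 rose by 0.38 ± 0.09. CYP1B1, chosen here after its values were seen, had 0.26 ± 0.07 with an edgeR adjusted p of 0.0328. camera called none of these lists as sets. Once the GC and length trends were removed it called the chaperone genes (0.00475) and the metallothionein and zinc genes (0.00257) higher and the macrophage markers (0.0119) lower, but none of the 3 with an estimated correlation (0.819, 0.549 and 0.549). Of single genes, 1 cell cycle gene was then higher and 0 lower, and no chaperone, hypoxia or metallothionein and zinc gene passed.

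In total, edgeR's quasi-likelihood test called 1037 genes higher and 1206 lower with EVs, with a median absolute log2 fold change of 0.33. At least 2-fold changes were fitted for 6 of the higher and 47 of the lower genes. Median GC was 38.9% in the genes that rose and 57.6% in those that fell, against 47.7% in all tested genes. Their median transcript lengths were 4491 and 2716 nt, against 3160.5 nt in all tested genes. Across 12823 genes, which are not independent replicates, Pearson's r of log2 fold change and GC content was −0.73. No gene passed when media 1, media 2, media 3, EV 2 or EV 3 was left out or when only the 2 groups were fitted, and 5599 passed without EV 1. After the GC and length correction 78 genes were higher and 45 lower, of which 64 were among those called before (2.85%), and of the genes named here CYC1, TREM2 and LGALS9 still passed.

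E/S, which holds both vesicles and soluble products, was compared with media to measure the response to all that the parasites release. CYP1B1 (chromosome 2, 38066973 to 38109902 on GRCh38) rose from 244.3 ± 9.76 to 368.3 ± 19.2 CPM (SD, n = 3 each), a log2 fold change of 0.59 ± 0.07 (SE) with an edgeR adjusted p of 0.00148, and no gene had a smaller one in this comparison. An antisense gene that overlaps CYP1B1, listed as C2orf58 and looked at for that reason only, was at 1.58 ± 0.115 CPM in media and 1.72 ± 0.215 CPM with E/S, and the sources do not say whether reads were counted by strand. Among the largest rises by the naming rule was RAP2A, a small GTPase (0.84 ± 0.22). DMC1, a recombinase of meiosis, had 0.62 ± 0.16, and RASGRP3, an activator of Ras-family GTPases, 0.60 ± 0.13. RPS6KB2, a kinase that phosphorylates ribosomal protein S6 (chromosome 11, 67428460 to 67435408), fell from 6.70 ± 0.35 to 2.92 ± 0.18 CPM, a log2 fold change of −1.20 ± 0.16. Among the largest falls were FBXL6 (−1.76 ± 0.41), PARP10 (−1.67 ± 0.28), CD320, the receptor for vitamin B12 uptake (−1.60 ± 0.33), and SIGIRR, an inhibitor of interleukin-1 receptor signalling (−1.41 ± 0.32). The GC content of these last 4 genes was 65.8%, 66.9%, 65% and 64%.

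Many metabolic and ribosomal genes fell with E/S. Of 40 ribosomal protein genes (median GC 51.2%), 26 fell and 0 rose, or 28 and 0 adjusted over the list alone, with a camera adjusted p of 2.48e-07. With the GC and length correction 2 fell and 2 rose. RPL18 had −0.51 ± 0.11, RPLP0 −0.45 ± 0.10 and RPS16 −0.57 ± 0.11. Of 38 oxidative phosphorylation genes (median GC 47.8%), 15 fell and 3 rose, or 16 and 3 adjusted over the list alone, with a camera adjusted p of 0.0393. COX8A (−0.93 ± 0.13), CYC1 (−0.84 ± 0.14) and COX4I1 (−0.56 ± 0.10) had the smallest p of this list. Of 23 glycolysis genes (median GC 55.7%), 13 fell and 1 rose, or 13 and 2 adjusted over the list alone, with a camera adjusted p of 0.0343. The correction left 0 lower and 1 higher and took their median from −0.33 to 0.01. GAPDH fell from 833.4 ± 39.3 to 566 ± 27.1 CPM, PFKL had −0.81 ± 0.22 and TPI1 −0.40 ± 0.10. With an estimated correlation the camera adjusted p = 0.731 for each of these 3 lists.

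Genes of growth control and sterol synthesis went both ways with E/S before the GC and length correction. After it 1 mTOR component was higher and 2 were lower. The cholesterol synthesis genes then had 4 higher and 0 lower, and the autophagy and lysosome genes also 4 and 0. The ATF4 genes had 0 and 1, the lipid handling genes 0 and 1 and the NRF2 genes 0 and 0. Of 32 mTOR pathway components (median GC 47.2%), 12 rose and 9 fell, or 12 and 10 adjusted over the list alone, and the median (−0.01) and the camera direction (up) differed in sign. PIK3CA, a PI3 kinase subunit (0.35 ± 0.07, GC 34.8%), rose, while MTOR (−0.29 ± 0.08, GC 52.2%) and RPS6KB2 (GC 62.3%) fell. Of 24 cholesterol synthesis genes (median GC 50.3%), 9 rose and 9 fell, or 9 and 11 adjusted over the list alone, with SC5D at 0.38 ± 0.09 (GC 38.6%) and LSS at −0.54 ± 0.13 (GC 58.3%). Of 23 ATF4 amino acid response genes (median GC 50.8%), 2 rose and 6 fell, or 3 and 6 adjusted over the list alone, PHGDH, the first enzyme of serine synthesis, at −0.75 ± 0.15. Of 27 autophagy and lysosome genes 6 rose and 8 fell, the same when adjusted over the list alone. Of 17 lipid handling genes 2 rose and 5 fell, also unchanged over the list alone. Of 18 NRF2 antioxidant genes 2 rose and 5 fell, or 4 and 5 adjusted over the list alone.

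Cell division and survival genes also went both ways with E/S. After the GC and length correction 3 cell cycle genes were higher and 1 lower, and 2 p53 and apoptosis genes higher and 1 lower. Of 24 cell cycle genes (median GC 46.2%), 9 rose and 4 fell, the same when adjusted over the list alone. TOP2A rose from 1537 ± 32.8 to 1906 ± 21.9 CPM, and RRM2, a subunit of the enzyme that makes deoxyribonucleotides, had 0.24 ± 0.06. MCM5 (chromosome 22, 35400063 to 35425430, GC 56.6%) fell from 37.3 ± 0.47 to 20.9 ± 2.12 CPM. Of 19 p53 and apoptosis genes (median GC 45.5%), 6 rose and 3 fell, as adjusted over the list alone. The survival genes MCL1 (0.24 ± 0.06) and BCL2 (0.20 ± 0.05) rose, and BAX, a pore-forming killer protein (−0.94 ± 0.18, GC 58.9%), fell. Of 19 hypoxia response genes (median GC 49.1%), 7 rose and 0 fell, as adjusted over the list alone, with BNIP3L at 0.33 ± 0.08, EGLN1 at 0.31 ± 0.07 and ERO1A at 0.33 ± 0.07. Of 20 chaperone genes 5 rose and 4 fell, or 6 and 6 adjusted over the list alone.

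Immune genes that passed with E/S were mostly lower before the GC and length correction, which left few of them past the threshold. After it 0 interferon-stimulated genes were higher and 1 lower, with 0 and 2 regulatory genes and 1 and 1 costimulatory genes. No interferon-gamma response, class II or inflammatory gene passed then. Of 34 interferon-stimulated genes (median GC 45.3%), 4 rose and 9 fell, as adjusted over the list alone, with BST2, a tether of budding virus, at −0.45 ± 0.12 and MX1, an antiviral GTPase, at −0.30 ± 0.11. IRF1 (−0.40 ± 0.10) was among 3 of 16 interferon-gamma response genes that fell, 2 adjusted over the list alone. NLRC5 (−0.54 ± 0.13) was among 9 of 17 class I presentation genes that fell while 2 rose, or 11 and 3 adjusted over the list alone (median GC 55.3%). Of the class I genes 1 was higher and 0 lower after the GC and length correction, and the median of the list went from −0.25 to 0.05. CD74 (−0.59 ± 0.13) was among 3 of 12 class II genes that fell while 1 rose, as adjusted over the list alone. LGALS9 (−0.73 ± 0.13), the inhibitory receptor gene LILRB4 (−0.32 ± 0.07) and TGFB1 (−0.63 ± 0.18) were among 4 of 19 regulatory genes that fell while 1 rose, as adjusted over the list alone. CD40 (−0.55 ± 0.16) was among 4 of 16 costimulatory genes that fell while 1 rose, as adjusted over the list alone. TNF (−0.46 ± 0.14) was 1 of 2 inflammatory genes of 20 that fell, 0 adjusted over the list alone.

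Some members of the receptor and cell type lists rose and others fell with E/S before the GC and length correction. After it 0 pattern recognition genes were higher and 0 lower. The macrophage markers then had 0 higher and 1 lower, and the classical monocyte markers 2 and 0. Of 20 pattern recognition genes (median GC 42.9%), 2 rose and 4 fell, as adjusted over the list alone. TLR2 (0.18 ± 0.05, GC 39.3%) and TLR4 (0.23 ± 0.07, GC 39.3%), which sense bacterial lipoproteins and lipopolysaccharide, rose. Of 12 macrophage markers (median GC 52.7%), 1 rose and 5 fell, as adjusted over the list alone, with TREM2 at −0.82 ± 0.14 and CD68 at −0.58 ± 0.14. Of 11 classical monocyte markers (median GC 46%), 3 rose and 1 fell, as adjusted over the list alone. MNDA (0.32 ± 0.08, GC 37.7%) rose and CSF3R, the receptor of the growth factor G-CSF (−0.64 ± 0.18, GC 60.9%), fell. Of 8 non-classical monocyte markers 1 rose and 3 fell, as adjusted over the list alone. Of 17 matrix remodelling genes 0 rose and 4 fell, of 12 alternative activation genes 1 rose and 0 fell, and these counts were also those adjusted over the list alone. Of 6 metallothionein and zinc response genes 1 rose and 2 fell, or 1 and 3 adjusted over the list alone, and of 6 tested B cell markers 1 fell, 0 adjusted over the list alone. camera called none of the lists in this and the previous 3 paragraphs.

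edgeR's quasi-likelihood test called 2431 genes higher and 2869 lower with E/S, with a median absolute log2 fold change of 0.35, and at least 2-fold changes were fitted for 10 and 295 of them. Median GC was 39.8% in the genes that rose and 58.1% in those that fell, with an r of −0.758 between log2 fold change and GC content across 12823 genes. Median transcript length was 4360 nt in the genes that rose and 2754 nt in those that fell. Between 2542 (without ES 1) and 4012 (without ES 2) genes passed when 1 library was left out, and 3297, 3017 and 3198 without media 1, media 3 and ES 3. After the GC and length correction 492 genes were higher and 231 lower, of which 416 were among those called before (7.85%). Of the genes named here CYP1B1, RASGRP3, PARP10, COX8A, CYC1, COX4I1, TREM2, LGALS9, LILRB4, BAX, MCL1, BCL2, MCM5, RRM2, EGLN1, RPS6KB2, SC5D and PHGDH still passed. TPI1 and TLR2 changed sign, with corrected values of 0.01 and −0.04.

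**Figure D2:**
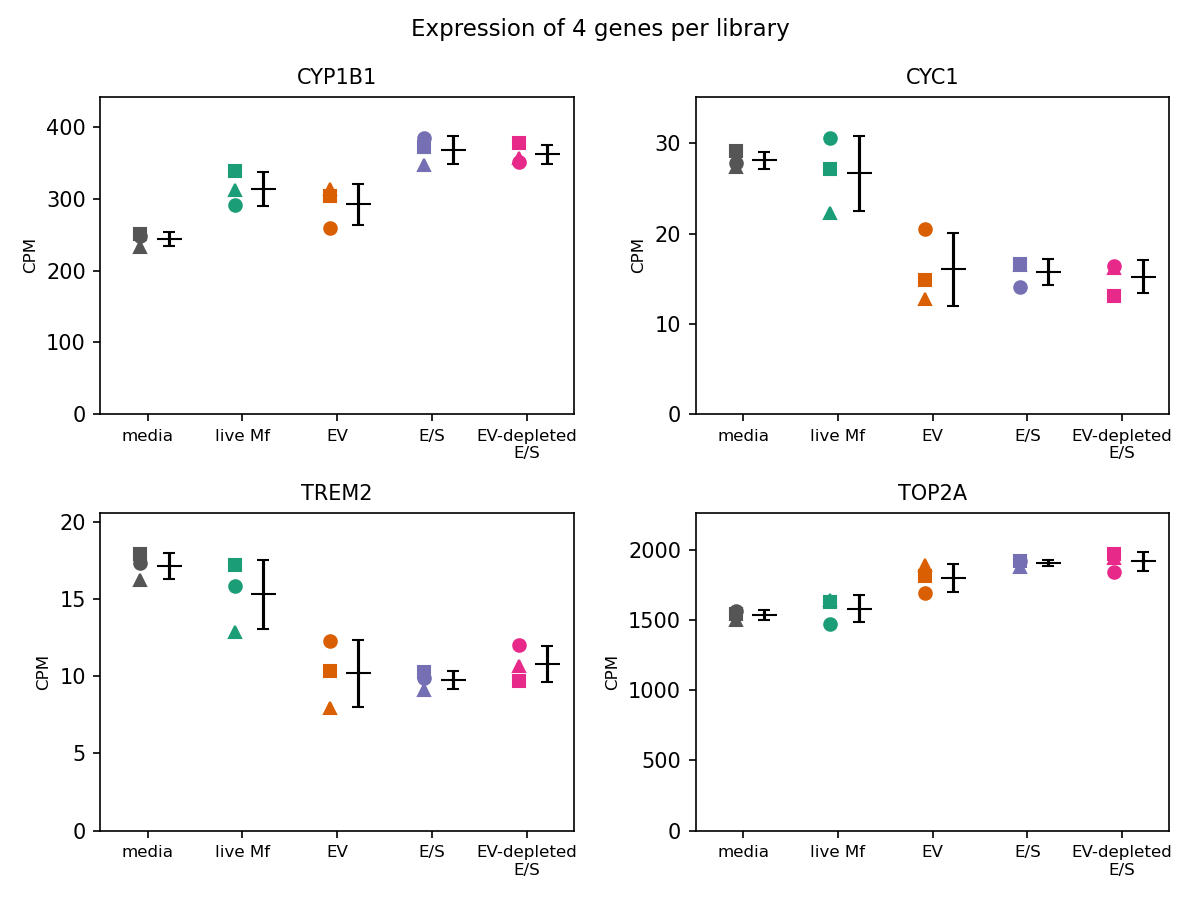
Expression in CPM of CYP1B1, CYC1, TREM2 and TOP2A is plotted for each library by group, with circles, squares and triangles for replicates 1, 2 and 3 and black bars for the mean ± SD of 3 libraries. CYP1B1 had means of 244.3 CPM in media and 368.3 CPM with E/S, and TOP2A means of 1537 CPM in media and 1906 CPM with E/S, while CYC1 and TREM2 were lower with E/S than in media.

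EV-depleted E/S was compared with media to measure the response to what remains once vesicles are taken out. CYP1B1, chosen here after its values were seen, rose to 362.1 ± 13.6 CPM (SD, n = 3) from 244.3 ± 9.76 CPM in media (n = 3), a log2 fold change of 0.57 ± 0.07 (SE) with an edgeR adjusted p of 0.00191. Among the largest rises by the naming rule were BCL2A1, a survival gene (1.09 ± 0.34, from 0.698 ± 0.406 to 1.5 ± 0.28 CPM), MYO5C, a motor protein gene (0.87 ± 0.22), and PDK4, a kinase that restrains pyruvate oxidation (0.74 ± 0.15). Among the largest falls were B3GAT3 (−1.86 ± 0.39), ZDHHC12 (−1.73 ± 0.37) and CLUH, which binds transcripts of mitochondrial proteins (−1.48 ± 0.23). Their GC content was 63.6%, 64.6% and 63.4%. MTOR fell from 50.02 ± 2.09 to 37.0 ± 2.98 CPM.

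Many metabolic genes fell with EV-depleted E/S as well. Of 40 ribosomal protein genes (median GC 51.2%), 0 rose and 22 fell, or 1 and 23 adjusted over the list alone. RPS16 had −0.56 ± 0.11 and RPLP0 −0.43 ± 0.10. The camera adjusted p of this list was 6.65e-05, and the camera adjusted p = 0.831 with an estimated correlation. camera did not call the other lists. Of 38 oxidative phosphorylation genes (median GC 47.8%), 5 rose and 14 fell, or 5 and 15 adjusted over the list alone, with CYC1 at −0.89 ± 0.15, COX8A at −0.77 ± 0.13 and COX4I1 at −0.57 ± 0.10. Of 23 glycolysis genes (median GC 55.7%), 2 rose and 12 fell, as adjusted over the list alone, GAPDH at −0.55 ± 0.13 and TPI1 at −0.37 ± 0.10. The GC and length correction left 2 higher and 0 lower and turned their median from −0.31 to 0.04. Of 27 autophagy and lysosome genes (median GC 50.7%), 6 rose and 9 fell, as adjusted over the list alone. LIPA (0.31 ± 0.07), which encodes a lysosomal hydrolase, rose, and the autophagy receptor gene SQSTM1 (−0.54 ± 0.12, GC 58%) fell. After the GC and length correction the ribosomal protein genes had 3 higher and 3 lower. The oxidative phosphorylation genes then had 1 and 6, and the autophagy and lysosome genes 4 and 1.

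Among immune genes, LGALS9 (−0.69 ± 0.13), LILRB4 (−0.25 ± 0.07) and TREM2 (−0.67 ± 0.14) fell with EV-depleted E/S, and NT5E, an enzyme that makes adenosine (0.37 ± 0.10), rose. In the regulatory list 2 of 19 rose and 5 fell, as adjusted over the list alone. Of 20 inflammatory genes (median GC 49.8%) 0 rose and 4 fell, 3 adjusted over the list alone, with TNF at −0.62 ± 0.14 and NFKB1 at −0.23 ± 0.07. CD74 (−0.58 ± 0.14) was among 2 of 12 class II genes that fell while 1 rose, as adjusted over the list alone. Of 12 alternative activation genes 2 rose, 1 adjusted over the list alone: the transcription factor KLF4 (0.26 ± 0.09, GC 55%) and CTNNAL1 (0.37 ± 0.07). Of 34 interferon-stimulated genes (median GC 45.3%) 4 rose and 6 fell, as adjusted over the list alone. HERC5 had 0.36 ± 0.10, SIGLEC1 −1.28 ± 0.25 (GC 60.6%) and LY6E −1.24 ± 0.28 (GC 64.2%). CD40 had −0.30 ± 0.16 and did not pass (edgeR adjusted p of 0.137). After the GC and length correction 1 regulatory gene was higher and 2 were lower. The interferon-stimulated genes then had 1 higher and 0 lower and the alternative activation genes 2 and 0. No inflammatory or class II gene passed then.

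Genes of cell division and survival went both ways, and the hypoxia genes that passed over all genes rose. Of 24 cell cycle genes (median GC 46.2%), 11 rose and 5 fell with EV-depleted E/S, or 11 and 6 adjusted over the list alone, TOP2A at 0.32 ± 0.06, RRM2 at 0.29 ± 0.06 and MCM5 at −0.72 ± 0.13. Of 19 p53 and apoptosis genes 6 rose and 2 fell, or 6 and 3 adjusted over the list alone, with the death receptor gene FAS at 0.46 ± 0.12, MCL1 at 0.25 ± 0.06 and BAX at −0.88 ± 0.18. Of 19 hypoxia response genes (median GC 49.1%) 8 rose and 0 fell, or 8 and 1 adjusted over the list alone, with INSIG2 at 0.40 ± 0.07, ERO1A at 0.37 ± 0.07 and EGLN1 at 0.34 ± 0.07. The GC content of these last 3 was 36.9%, 38.7% and 44.1%. After the GC and length correction 2 cell cycle genes were higher and 1 lower. The p53 and apoptosis genes then had 3 higher and 1 lower, and the hypoxia response genes 3 and 0.

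edgeR's quasi-likelihood test called 2578 genes higher and 2926 lower with EV-depleted E/S, with a median absolute log2 fold change of 0.36 and at least 2-fold changes for 16 and 313. Median GC was 40.1% in the genes that rose and 57.8% in those that fell, with an r of −0.779 between log2 fold change and GC content. Median transcript length was 4034 nt in the genes that rose and 2925.5 nt in those that fell. Without EV-depleted E/S 2 the test called 2253 genes, and without media 3 it called 3548. After the GC and length correction 806 genes were higher and 396 lower, of which 743 were among those called before (13.5%). Of the genes named here CYP1B1, MYO5C, PDK4, B3GAT3, ZDHHC12, CLUH, CYC1, COX4I1, LGALS9, LILRB4, KLF4, CTNNAL1, EGLN1, BAX, MCL1, MCM5 and RRM2 still passed, and TPI1 changed sign to 0.04.

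**Figure D3:**
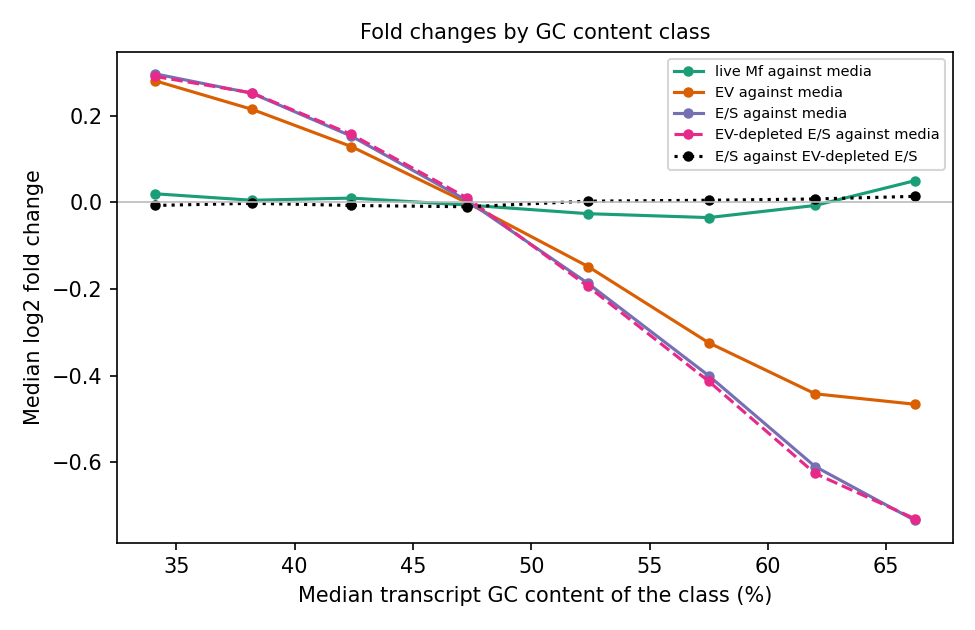
The median log2 fold change of genes with at least 1 CPM is plotted against the median GC content of 8 GC classes, in percent, with one line for each of 5 comparisons. Between media and E/S the medians run from 0.30 in the lowest class (232 genes) to −0.73 in the highest (220 genes), while between E/S and EV-depleted E/S they stay within −0.01 and 0.01.

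E/S was compared with EV-depleted E/S to measure what the vesicles add to the released products. No gene passed. CYP1B1, chosen here after its values were seen, was at 368.3 ± 19.2 CPM with E/S and 362.1 ± 13.6 CPM without the EVs (SD, n = 3 each), a log2 fold change of 0.02 ± 0.07 (SE). Its sign turned to −0.01 without ES 1. Of the genes that the naming rule admits, the 5 with the smallest p were KCNC4, a potassium channel gene (0.56 ± 0.16), PGBD2 (−0.30 ± 0.09), ZNF81 (0.33 ± 0.10), MNT (0.47 ± 0.14) and the pseudogene BMS1P2 (2.16 ± 0.53), which shares reads with near-identical copies and is uncertain. The antiviral genes IFIT1 and MX1 had −0.38 ± 0.13 and −0.27 ± 0.11.

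No list was called between E/S and EV-depleted E/S, and no member of the 28 tested lists passed over all genes or adjusted over the list alone. edgeR's quasi-likelihood test called 0 of 14953 genes, with 300 at an unadjusted p under 0.05 and a smallest adjusted p of 1, and DESeq2 called 1. Fitting only these 2 groups called 7 higher and 2 lower. In simulated data this comparison recovered 92% of 2-fold, 70% of 1.5-fold and 32% of 25% changes, so many changes of under 1.5-fold would not have been detected. Those data had one spread per gene and no GC trends, and the planted changes eased the adjusted threshold, so the real shares may be lower. The r between log2 fold change and GC content was 0.028.

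EVs were compared with live Mf directly, because a gene called against media in one group and not in the other is not thereby shown to differ. TNF was at 7.47 ± 1.04 CPM with live Mf and 4.62 ± 0.71 CPM with EVs (SD, n = 3 each), a log2 fold change of −0.68 ± 0.14 (SE) with an edgeR adjusted p of 0.017. HGF, the hepatocyte growth factor gene, rose from 5.77 ± 0.47 to 8.87 ± 1.69 CPM (0.61 ± 0.14). ZBED6, a transcriptional repressor (0.96 ± 0.21), and BIRC3, an inhibitor of cell death (0.67 ± 0.21), were, with HGF, among the largest rises by the naming rule. ZBED6 lies within ZC3H11A, so reads of the 2 genes can be confused. ARSA, a lysosomal sulfatase (−1.37 ± 0.30, GC 66%), was among the largest falls. SNURF had −1.60 ± 0.32, but it overlaps SNRPN and the 2 can share reads, so this value is uncertain.

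Some mitochondrial, ribosomal and glycolytic genes were lower with EVs than with live Mf. Of 40 ribosomal protein genes (median GC 51.2%) 0 rose and 9 fell, or 24 adjusted over the list alone, with a camera adjusted p of 3.01e-11. RPL27 had −0.31 ± 0.07, RPS10 −0.40 ± 0.09 and RPS16 −0.42 ± 0.11. Of 38 oxidative phosphorylation genes (median GC 47.8%) 0 rose and 8 fell, or 14 adjusted over the list alone, with a camera adjusted p of 7.34e-04. CYC1 had −0.73 ± 0.14, COX4I1 −0.45 ± 0.10 and COX8A −0.54 ± 0.13. Of 23 glycolysis genes (median GC 55.7%) 1 rose and 2 fell, or 1 and 6 adjusted over the list alone, with a camera adjusted p of 0.00138. HK3 (−1.06 ± 0.25) and TPI1 (−0.37 ± 0.10) fell and PDK1 (0.30 ± 0.08, GC 39.8%) rose. PSMB8, an immunoproteasome subunit (−0.28 ± 0.07), was the 1 of 17 class I presentation genes (median GC 55.3%) to fall, or 6 adjusted over the list alone, with a camera adjusted p of 0.038. With an estimated correlation the camera adjusted p = 0.712 for the oxidative phosphorylation genes and 0.761 for the other 3 lists. After the GC and length correction the ribosomal protein (1.57e-07) and oxidative phosphorylation genes (1.44e-06) were still called and the glycolysis genes (0.288) were not. The class I genes were not called either (0.358) and their direction turned to up, while the metallothionein and zinc genes were called higher (4.37e-06). No member of these 5 lists passed after the correction, and with an estimated correlation the 3 calls were lost (camera adjusted p of 0.925 for the ribosomal protein genes and 0.281 for the other 2). With the correction and the replicate number as a block in these 2 groups the glycolysis genes were called lower (0.0294), though not with an estimated correlation (0.815).

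In the other lists, RICTOR (0.34 ± 0.06, GC 36.5%) rose and RPTOR (−0.59 ± 0.16, GC 59.8%) and LAMTOR2 (−0.72 ± 0.16, GC 57.6%) fell between live Mf and EVs. These encode a subunit of each mTOR complex and a scaffold of the lysosomal surface, and 3 of 32 mTOR components rose and 5 fell, or 7 and 9 adjusted over the list alone. SLC30A1 (0.40 ± 0.09) and TLR2 (0.20 ± 0.05) rose, and LGALS9 (−0.50 ± 0.13), TREM2 (−0.58 ± 0.14), MYD88 (−0.26 ± 0.08) and the calcium-binding protein gene S100A9 (−0.28 ± 0.08) fell. In the cell cycle list 1 of 24 rose, TOP2A (0.19 ± 0.06), and 1 fell, MCM5 (−0.51 ± 0.13), or 2 and 4 adjusted over the list alone. CYP1B1, chosen here after its values were seen, had −0.10 ± 0.07 and did not pass (edgeR adjusted p of 0.322). It passed, lower with EVs, when the replicate block in these groups was joined with the GC and length correction.

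edgeR's quasi-likelihood test called 744 genes higher and 621 lower with EVs than with live Mf, with a median absolute log2 fold change of 0.32 and at least 2-fold changes for 4 and 39. Median GC was 38.9% in the genes that rose and 58.2% in those that fell, with an r of −0.771 between log2 fold change and GC content. Median transcript length was 6829.5 nt in the genes that rose and 2251 nt in those that fell. No gene passed without live Mf 1 or EV 2 or when only the 2 groups were fitted, 51 passed without live Mf 2 and 42 without EV 3, while 4683 passed without live Mf 3 and 5044 without EV 1. The replicate numbers may pair these 6 libraries, though that was read from the same values and can be chance. With the number as a block over all 15 libraries 1491 genes were higher and 1472 lower, with the block in these 2 groups alone 2709 and 2662, and with only the 2 groups and the block 2570 and 2456. The block in these 2 groups together with the GC and length correction gave 282 and 220. After the GC and length correction 6 genes were higher and 9 lower, of which 11 were among those called before, without the block, and of the genes named here SNURF still passed while S100A9 and TOP2A changed sign, to 0.07 and −0.01.

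The 4 responses to exposure were compared with one another across 14953 genes, which are not independent replicates. The log2 fold changes of E/S and EV-depleted E/S had a Pearson's r of 0.801, those of EVs and E/S of 0.778 and those of EVs and EV-depleted E/S of 0.748. Over 50 draws of unchanged groups, in which the media libraries were simulated too, the means were 0.513, 0.52 and 0.506. They lie above 0 because the comparisons of a draw share their simulated controls. The covariances were 0.146, 0.115 and 0.113, against simulated ones of 0.0382, 0.0382 and 0.0377. For live Mf the r was 0.383 with EVs, 0.317 with E/S and 0.317 with EV-depleted E/S, against simulated means of 0.511, 0.512 and 0.505. The covariances of live Mf were 0.0327, 0.0326 and 0.0334, each under its simulated value of 0.0381, 0.0379 and 0.038. These simulated values may be too high for the real media libraries.

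E/S and EV-depleted E/S shared 2077 genes called higher and 2353 called lower, where independent lists of these sizes would share 419.1 and 561.4. EVs and E/S shared 964 and 1135 (168.6 and 231.4 if independent), and EVs and EV-depleted E/S shared 937 and 1100 (178.8 and 236). In these 3 pairs 0 genes were called in opposite directions, and the simulated groups, drawn without GC trends, shared 0 calls. The 3 media libraries are too few to be split into 2 sets of 2, so part of these excesses may come from the shared controls. Much of the overlap went with the trends on GC content and length, which were not told apart. After the GC and length correction EVs and E/S shared 70 higher and 33 lower (2.6 and 0.7 if independent). EVs and EV-depleted E/S then shared 60 and 29 (4.2 and 1.2). The overlaps with EVs also rest on the libraries included, as no gene was called for EVs without media 1, media 2, media 3, EV 2 or EV 3.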

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

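The GC and length correction, the thinning to the smallest library and the comparison of GC slopes within groups were chosen only after the fold changes were seen to follow GC content. The block in EVs and live Mf alone and the sorting of splits by pairs were also added after results were seen. The contrast of EVs with live Mf, the left-out libraries and the count over other splits of the libraries were planned.

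The responses to EVs and to live Mf differed in 1365 genes in the direct contrast, 744 higher and 621 lower with EVs. This difference between groups was tested as such, with edgeR's quasi-likelihood test, and without a block it rests on which libraries are included. It fell to 0 genes without live Mf 1 or EV 2, to 51 without live Mf 2 and to 42 without EV 3, and it rose to 4683 without live Mf 3 and to 5044 without EV 1. Of the 10 splits of the 6 libraries into 3 and 3, 2 gave as many genes, the real one included. Another split called 5083 genes, several times the real 1365. Of the 9 other splits 3 called genes, but apart from the one with 5083 they called only 1 gene each. The split with 5083 genes points to a structure of the libraries that crosses the 2 groups. That split set live Mf 1, live Mf 2 and EV 1, with the 3 highest GC slopes (0.314, 0.190 and 0.103), against the other 3, and it parted 1 of the 3 pairs that the replicate numbers form here. The real split parts all 3 pairs. Of the 4 splits that do, the real one called 1365 genes and each of the other 3 called 0. With the pairs as a block in these 2 groups it called 5371 and the others again 0, and 4 splits are too few for a share under 0.05. Much of the difference within pairs also went with GC content and length, since the block with the GC and length correction left 282 higher and 220 lower.

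The other comparisons also have 10 splits each, too few for a share under 0.05. EVs against media had 2243 genes in the real split and 0 in the highest other split, with 1 split as large, the real one. E/S against media had 5300 and 0, and EV-depleted E/S against media 5504 and 0, again with 1 split as large. Live Mf against media and E/S against EV-depleted E/S had 0 genes in the real and in every other split, so that all 10 were as large.

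GC-rich genes were lower and GC-poor genes higher after exposure to E/S. Unequal depth alone is argued against as the source of the calls, since after thinning to the smallest library 88.7% of the called genes still passed in the same direction. Thinning takes reads away at random and leaves a GC trend in place. It therefore cannot test a preparation difference that goes with library size. Exposure as the only source of GC trends is argued against too: with the same exposure the EV libraries spanned 0.348 in slope, 1.05 times the distance of 0.331 between the media and E/S means. The live Mf libraries spanned 0.274. The spans were smaller in media (0.006), E/S (0.073) and EV-depleted E/S (0.161), so the argument rests on the EV and live Mf groups. A difference between libraries in how GC content or length affects capture or amplification remains a candidate explanation for most of the calls. Removing each library's trends on both left only 7.85% of the genes called between E/S and media. An effect of E/S on GC-rich transcripts stays open as well, since all 6 E/S and EV-depleted E/S libraries had slopes below all 3 media libraries and the labels give no preparation batches.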

How the results depend on the processing

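The GC and length correction, the thinning, the fits without both EV 1 and live Mf 3 and those with a block in EVs and live Mf alone were chosen after seeing the data, and the other alternatives before the data were examined. Except for the GC and length correction, and unless a reason follows from fewer libraries or other genes tested, the cause was not tested.

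With the GC and length correction the genes higher and lower were 1 and 0 for live Mf, 78 and 45 for EVs, 492 and 231 for E/S, 806 and 396 for EV-depleted E/S, all against media, and 6 and 9 for EVs against live Mf. Of 152 named gene values past the threshold, 47 stayed, 100 no longer passed and 5 changed sign: TPI1 with E/S (0.006) and EV-depleted E/S (0.037), TLR2 with E/S (−0.044), and S100A9 (0.066) and TOP2A (−0.014) in EVs against live Mf. Lists called went to 0 for live Mf, 5 for EVs and 3 for EV-depleted E/S. The correlations of responses became 0.628 for E/S and EV-depleted E/S, 0.61 for EVs and E/S, 0.559 for EVs and EV-depleted E/S, and 0.483, 0.424 and 0.411 for live Mf with EVs, E/S and EV-depleted E/S.

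DESeq2 called 5 higher for live Mf, 1800 higher for EVs, 1 higher for E/S against EV-depleted E/S, and 1500 higher and 1019 lower for EVs against live Mf. It shared 94.2% of the genes called for EVs, 91.8% for E/S, 93.4% for EV-depleted E/S and 94.3% for EVs against live Mf, and 11 of the 152 named values no longer passed. Without the low-count filter 23 genes were higher and 18 lower for live Mf, 1912 lower for EVs, 20 higher and 21 lower for E/S against EV-depleted E/S, and 1211 higher and 1634 lower for EVs against live Mf. Lists called were then 6 for EVs, 5 for E/S and 3 for EV-depleted E/S, and the correlations, now with scarce genes, 0.569, 0.554, 0.545, 0.506, 0.507 and 0.488 in the order above. Fitting only the 2 groups called 0 higher and 0 lower for EVs and for EVs against live Mf, and 7 higher and 2 lower for E/S against EV-depleted E/S, and 58 of the 152 named values no longer passed. RLE size factors moved no count of genes by over 1.5 times, 1 named value no longer passed, and lists called for live Mf went to 1.

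Libraries of one number deviated alike for EVs and live Mf, possibly by chance, and not in the other groups compared. Over all groups 6 of 30 pairs with one number had a correlation over 0.1 (median 0.004, range −0.155 to 0.46), and 9 of 15 libraries correlated best with their own number. The replicate block gave 1744 higher and 1892 lower for EVs, 1491 higher and 1472 lower for EVs against live Mf, and 7 lists for EVs and 2 for EV-depleted E/S. It ended no call of a named gene. The block in EVs and live Mf alone called 2709 higher, 2662 lower and 7 lists between them, the lysosome, matrix and macrophage lists (camera adjusted p of 0.0315, 0.0314 and 0.0314) being added to the 4 but not called with an estimated correlation (0.656, 0.656 and 0.455), and 27 of 27 named values still passed. Fitted with only these 2 groups it called 2570 and 2456 and 6 lists, with 1 named value no longer past the threshold. Together with the GC and length correction it called 282 and 220 and 4 lists, now with the metallothionein genes (4.69e-05, or 0.348 with an estimated correlation) in place of class I, and of the 27 named values 10 stayed, 15 no longer passed and 2 changed sign, while CYP1B1 (−0.205) passed.

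Leaving out 1 library gave 0 to 2661 higher and 0 to 2938 lower for EVs, 1202 to 1762 and 1335 to 2250 for E/S, 1003 to 2472 and 1250 to 2785 for EV-depleted E/S, and 0 to 2393 and 0 to 2651 for EVs against live Mf. For EVs 0 passed without media 1, media 2, media 3, EV 2 or EV 3, and 5599 without EV 1. Lists called ranged from 0 to 7 for live Mf, 2 to 7 for EVs, 1 to 5 for E/S, 1 to 2 for EV-depleted E/S, 0 to 2 for E/S against EV-depleted E/S and 2 to 7 for EVs against live Mf. Of 912 named values past the threshold, 308 no longer passed. CYP1B1 in E/S against EV-depleted E/S ranged from −0.011 (without ES 1) to 0.065 (without ES 3). Without both EV 1 and live Mf 3 the counts were 8 and 4 for live Mf, 3207 and 3338 for EVs and 3373 and 3471 for EVs against live Mf, with 7 lists for live Mf, 3 for EV-depleted E/S, 1 for E/S against EV-depleted E/S and 7 for EVs against live Mf.

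With an estimated correlation 0 lists were called in each comparison. With fry's directional p there were 0 for live Mf, 11 for E/S, 5 for EV-depleted E/S and 1 for EVs against live Mf. Of simulated changes by 25% between media and E/S 24% were recovered, so small changes can be missed, and the simulation does not tell depth from the spread or number of libraries.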

Other observations

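The genes of the first paragraph and the tests of the last were chosen only after results were seen. The tests on CYP1B1 were set after its fold change was seen and before their own results.

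Some genes moved with E/S and still passed after the GC and length correction. With it THBD, which encodes the anticoagulant receptor thrombomodulin, had a log2 fold change of 0.48 with an edgeR adjusted p of 0.00323 (0.20 ± 0.05, SE, before). LHX2, a developmental transcription factor, had 1.02 (0.51 ± 0.13 before), BASP1, a membrane-bound signalling protein, 0.50 (0.19 ± 0.06 before), GADD45A, a growth arrest gene, 0.48 (0.31 ± 0.07 before), and HMGB2, a chromatin protein of dividing cells, 0.24 (0.15 ± 0.05 before). CDK10, a cyclin-dependent kinase gene, had −0.93 (−1.08 ± 0.18 before), PPP2R1A, the scaffold of protein phosphatase 2A, −0.44 (−0.67 ± 0.13 before) and ATP6V0B, a subunit of the vacuolar proton pump, −0.35 (−0.57 ± 0.09 before). BASP1 and HMGB2 no longer passed the uncorrected test without ES 1, ES 2, media 1 or media 3.

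After the correction 407 genes were higher and 158 lower with both E/S and EV-depleted E/S, and 0 went opposite ways, where independent lists would share 26.5 and 6.1. Part of this excess may come from the shared media libraries. The oxidative phosphorylation genes were called lower after the correction with EVs, E/S and EV-depleted E/S (camera adjusted p of 2.60e-04, 0.00146 and 0.0131), and the ribosomal protein genes likewise (2.60e-04, 1.38e-04 and 0.00376). Few ribosomal protein genes still passed, however: 1 higher and 0 lower with EVs, 2 and 2 with E/S and 3 and 3 with EV-depleted E/S. The glycolysis genes were no longer called with EVs and E/S (0.25 and 0.999), and the hypoxia response genes were called higher with E/S and EV-depleted E/S (0.0315 and 0.00712). With an estimated correlation none of these calls held (camera adjusted p from 0.549 to 0.986).

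CYP1B1 was higher with E/S than in media, and the trends on GC content and length are argued against as its whole cause. The corrected log2 fold change was 0.485 (95% interval 0.368 to 0.602) against 0.592 before. The lower bound lies above 0.296, where the trends and the remainder would have equal shares. CYP1B1 is a textbook target of the aryl hydrocarbon receptor, and one hypothesis is that E/S, or something added with it, may activate that receptor. Of 8 other targets listed beforehand, 4 reached 1 CPM, and 3 of these rose after the correction at an unadjusted p under 0.05, beside 3029 of 14953 genes past that bound in either direction: AHRR (0.325), TIPARP (0.137) and NQO1 (0.173). AHRR rose only with the correction (−0.059 before), SERPINB2 did not rise (−0.107), and CYP1A1, the best known target, stayed at 0.151 CPM, so the hypothesis rests on few genes.

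Cell cycle genes were high and several monocyte genes low in every library. Carry-over of the other listed blood cells is argued against, since the highest median of their marker lists in any library was 0.418 CPM. BANK1 at 27.1 CPM, MYL9 at 13.2 and CXCR2 at 36.2 were the most abundant members. The protocol names a magnetic bead isolation that would remove such cells. It counts here only if the cells were the donor monocytes of the labels, which is open. Dividing cells in the cultures stay open as an explanation. Of the 24 cell cycle genes, 24 had a mean of at least 1 CPM and 18 of at least 100 CPM, but division itself was not measured. The cell cycle genes had a higher median than the classical monocyte markers in 15 of 15 libraries, but this restates the pattern and tests no explanation of it. What the cells are was not tested, and the labels' words (donor monocytes, cell lines, dendritic cells) leave it open. The responses above are therefore not shown to be those of resting donor monocytes.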
